A study of Arabidopsis thaliana with 2 samples.

How the data were processed

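RNA from whole seedlings of Arabidopsis thaliana (accession Columbia-0) was compared on 2 two-colour Agilent arrays, each carrying 1 biological replicate of treated seedlings and 1 of control seedlings. Per the labels' protocols, seedlings 14 days old were lifted from agar holding mineral salts and sugar into water and kept in the light in a closed desiccator with 2.3 ppb trans-2-hexenal. The treated sample was taken at 6 h and the control at 0 h, so the control did not go through the transfer, the desiccator or the hours in the light. Treated RNA was labelled with Cy5 and control RNA with Cy3 on both arrays, per the labels, with no dye swap, so a dye effect cannot be separated from the treatment. One sentence of the labelling protocol names the Cy5 sample as treated with another compound, while the titles, the source names and the series design all give trans-2-hexenal; the titles were followed. The labels call the arrays biological replicates, and do not say whether the seedlings came from separate cultures. The p-values of single genes therefore measure the spread between these 2 pairs of samples.

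The deposited scanner files hold, per the file headers, the mean intensity of each spot, the median intensity of its local background and flags for each spot and dye, from Agilent Feature Extraction 10.5.1.1 at a scan resolution of 5 µm. The submitters' processing notes name Agilent Feature Extraction 8.5.1.1. The files also hold a log10 ratio of Cy5 over Cy3 that, per the file headers, follows Agilent's background subtraction and dye normalisation. The deposited series value table matched that log10 ratio to within 0.005 for the 43774 and 43758 spots it gives, so its scale, centring and direction are those of the scanner's ratio; the median of each column was 0. Both arrays lay on 1 slide and in the same scan, so a slide term could not be fitted.

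Of 45220 spots, 1417 were control spots and 43803 carried 43603 distinct probes. The intensities were background-corrected by normexp with an offset of 50 in limma 3.58.1 under R 4.3.3, with the package data.table at version 1.17.8, and log2 ratios of Cy5 over Cy3 were normalised within each array by loess, with control spots at weight 0. Spots marked as outliers in the files, 15 on replicate 1 and 16 on replicate 2, were left out, and spots of one probe were averaged. A probe was kept if it was well above background on both arrays in the treated or in the control channel, which kept 30197 probes, 28051 of them with a locus code. The kept probe with the highest mean intensity stood for its gene. This gave 20600 genes, of which 20405 matched a locus in the RefSeq gene table of assembly TAIR10.1, used for symbols alone; the probes of 377 genes match several loci in the array's own annotation. Probe positions are those of the array file, whose build is named ath1:Jan2004. Well above background were 67.8% and 65.0% of probes in the control channel and 71.5% and 68.6% in the treated channel of replicates 1 and 2, and the number of saturated spots was 0. The number of arrays limits the precision.

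The log2 ratios were fitted with an intercept in lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 2 arrays leave 1 residual degree of freedom per gene, to which eBayes added 2.55. Errors are SDs over the 2 arrays (n = 2). Of a probe below background on both arrays of a channel, the ratio is given as a lower bound from single-channel values after Aquantile normalisation, which is open to dye bias.

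Before the data were examined, 27 gene lists were fixed and tested with camera at a preset correlation of 0.01. Camera at an estimated correlation and fry were run beside it. At the preset value camera takes list members as nearly independent, so its p-values leave out spread that members share between the 2 pairs. Of 386 genes listed by name 375 were measured, and the cytosolic ribosomal and proteasome lists came from the array's description column. The genes named were fixed by a rule: the 10 largest rises and 10 largest falls past the test with the same sign on both arrays, filled where too few passed with the next largest at least 2-fold on both arrays, and up to 4 members of each list with the largest ratios. Alternatives fixed at the same time were no background subtraction, an offset of 16, median centring without loess, the deposited log10 ratio and value table, no filter or a stricter one, the mean of all kept probes, a trended prior, TREAT against a log2 ratio of 0.5, separate channels with no replicate block, and each replicate left out.

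The steps were tested on simulated data for the comparison of 6 h trans-2-hexenal against control, with 200 changed among 33250 probes. With a spread smaller than that of these arrays (variance 0.05), 0% of log2 changes of 1, 70.1% of those of 2 and 89.4% of those of 3 were called, with 7 false calls among 113. With the spread fitted over those probes on these arrays (prior variance 0.0977, against 0.128 over the genes tested), none of the changes of 1, 2 or 3 was called by limma, a count of 0 in which 77.6%, 94.0% and 100% had an unadjusted p under 0.05. When the changes were 3, 5 and 7 at that spread, 31.3%, 89.6% and 92.4% were called, with 9 false calls among 151. Camera called 5 of 5 shifted lists and 1 of 15 lists that were not shifted. The simulated noise was drawn independently for each probe, so this does not test lists whose members vary together. The share of changed probes was also small, while 6237 of the 20600 genes tested had an unadjusted p under 0.05 in limma. Since that share and the spread differ from those of the genes tested, the simulated shares called are not the power in the real data.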

Results

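The data compare the transcripts of Arabidopsis seedlings after 6 h with trans-2-hexenal with those of control seedlings taken at 0 h. Trans-2-hexenal is a volatile aldehyde that leaves release when wounded, with a reactive unsaturated carbonyl group. There were 2 arrays, each 1 biological replicate, and 20600 genes were tested. Values are mean log2 ratios of treated over control ± SD (n = 2) unless stated otherwise. The control was sampled before the transfer to water, so each ratio holds the treatment together with the handling and the time that passed.

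Genes of the heat shock response had the largest ratios. Those that rose past the test are given first, in order of their ratio. HSP22.0 (AT4G10250), a small heat shock protein of the endoplasmic reticulum, rose 317-fold, a log2 ratio of 8.31 ± 0.32 (adjusted p = 0.0373, limma). Its probe lies on chromosome 4 from 6371055 to 6371114 in the array's build, ath1:Jan2004. AT1G52560, described on the array as similar to class I small heat shock proteins, rose by 8.30 ± 0.16, and its probe lies on chromosome 1 from 19578457 to 19578516. HSP21 (AT4G27670), the small heat shock protein of the chloroplast, rose by 8.12 ± 0.03, and HSP70B (AT1G16030), a chaperone of the HSP70 family, by 8.06 ± 0.03. AT1G54050, a class III small heat shock protein, rose by 7.68 ± 0.19, HSP17.4 by 7.15 ± 0.12, HSP18.2 by 6.83 ± 0.23 and HSP17.6II by 6.81 ± 0.31. Outside the chaperones, AT5G05220, described on the array only by similarity to a hypothetical protein, rose by 6.81 ± 0.04, and AT1G03070, annotated as glutamate binding, by 6.56 ± 0.07. The remaining rises past the test were HSP17.6A, HSA32, HSP15.7, HSP70T-2, HSP17.6C, the β-glucosidase gene BGLU28 and AT1G72660, annotated as a putative GTP-binding protein, from 6.01 to 6.52. Other members of the heat shock list had ratios as large but differed more between the arrays and did not pass (adjusted p = 0.0618, limma). Among them were HSP17.6A-CI at 7.44 ± 1.08, MBF1C at 7.29 ± 1.35, HSP70 at 6.54 ± 1.87 and HSP101 at 6.41 ± 1.13.

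In all, 17 genes rose and 0 fell at an adjusted p under 0.05 in limma, and all 17 changed at least 2-fold. All 17 had the same adjusted p of 0.0373, and the lowest ratio on a single array was 5.95. At an unadjusted p under 0.05 there were 3344 higher and 2893 lower genes, where chance gives 1030 in all. On both arrays, 1644 genes were at least 2-fold higher and 1022 at least 2-fold lower. The count depended on the processing: with the deposited log10 ratios, with the deposited value table or with no filter on dim probes, limma called 0 genes (6353, 6344 and 7437 at an unadjusted p under 0.05), and with median centring in place of loess it called 1481, of which 1272 rose and 209 fell. With separate channels and no replicate block, 2098 genes rose and 1371 fell.

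None of the lower genes passed the test, and the following are the 10 lowest among those at least 2-fold lower on both arrays. The peroxidase gene AT5G19890 was lowest, at -4.71 ± 0.72 (adjusted p = 0.0618), followed by AT5G62360, of a family of invertase and pectin methylesterase inhibitors, at -4.16 ± 0.01 and NRT1.5 (AT1G32450), a nitrate transporter of the root, at -4.12 ± 0.45. Then came AT3G20380, which carries a MATH domain, at -4.05 ± 0.03, and the glucosinolate genes CYP83A1 at -3.78 ± 0.83, IPMI1 at -3.66 ± 0.63 and MAM3 at -3.64 ± 0.30. The F-box gene AT2G36090 was at -3.64 ± 0.29 and AT2G28780, annotated as unknown, at -3.59 ± 0.34. AT1G73600, for a phosphoethanolamine N-methyltransferase, was at -3.57 ± 2.57 (adjusted p = 0.127), with a probe that matches 2 loci.

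**Figure D1:**
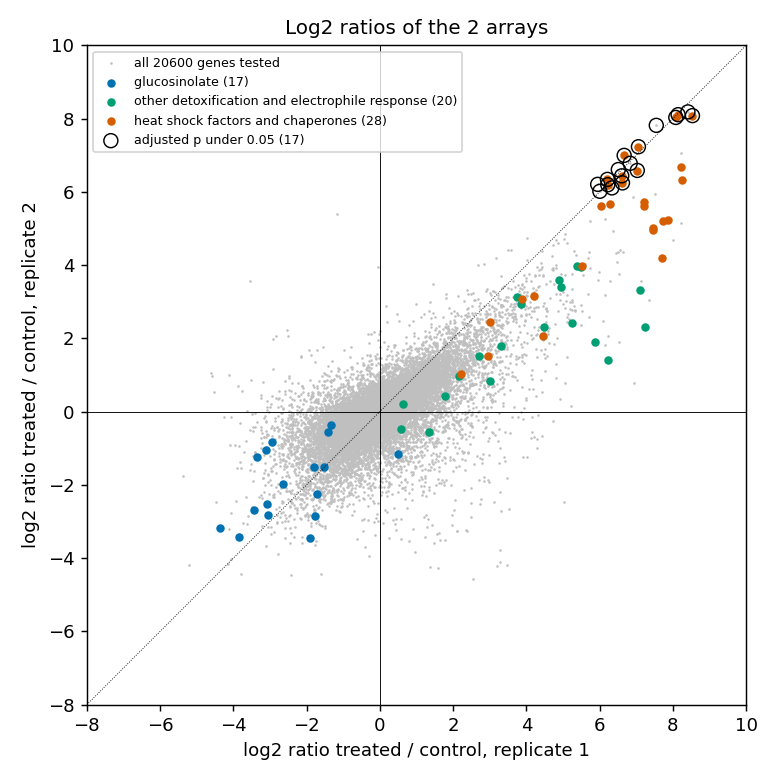
Log2 ratio of treated over control on replicate 1 (x axis) against replicate 2 (y axis) for the 20600 genes tested, with 3 gene lists in colour, the 17 genes at an adjusted p under 0.05 in circles and a dotted line of equal ratios. The circled genes lie at 5.95 or higher on both arrays, close to the line, since the test favours ratios that agree.

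The heat shock list rose as a whole. All 28 measured members were higher on both arrays, with a mean log2 ratio of 5.83 (camera adjusted p = 2.18e-22; adjusted p = 0.693 with an estimated correlation). Over all genes 10 members rose, and 28 of 28 passed when adjusted over the list alone. HSP17.6A-CI, at 7.44 ± 1.08, had an adjusted p of 0.0618 over all genes. Chaperones of the endoplasmic reticulum fell as a list, with a mean of -0.84 (camera adjusted p = 0.00128; adjusted p = 0.693 with an estimated correlation). The mean was -0.39 on replicate 1 and -1.29 on replicate 2, and with median centring -0.27, or -0.56 relative to the median of all genes. Of the 12 measured, 7 fell and 1 rose when adjusted over the list alone. The lectin chaperones CRT1, CNX1 and CRT2 were at -2.03 ± 0.04, -2.03 ± 0.14 and -1.95 ± 0.06, while the co-chaperone ERDJ3A was at 4.04 ± 1.82. Genes of proteasome subunits rose as a list, with a mean of 0.66 and 30 of 31 members higher on both arrays (camera adjusted p = 2.26e-06; adjusted p = 0.693 with an estimated correlation); the highest were AT3G26340 at 1.76 ± 0.65, AT1G04810 at 1.42 ± 0.44, AT5G23540 at 1.39 ± 0.42 and PBC2 at 1.06 ± 0.00. Cytosolic ribosomal protein genes were lower as a list, with a mean of -0.34 over 183 members and 136 lower on both arrays (camera adjusted p = 4.58e-07; adjusted p = 0.693 with an estimated correlation), at -0.20 on replicate 1 and -0.48 on replicate 2. With median centring, which moved the median of all genes from -0.04 to 0.29, the mean was 0.17, or -0.12 relative to that median, and the call was lost (adjusted p from 6.28e-08 to 0.424 over 10 other settings). Among them SAG24 stood at 4.14 ± 1.55, AT3G16780 at -1.28 ± 0.08 and AT1G23410 at -1.25 ± 0.43, and AT5G63070, not well above background in either control, was at least 2.22-fold higher (adjusted p = 0.0698).

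Outside the heat shock list, none of the 561 other list members tested passed over all genes in limma, a count of 0 beside 111 higher and 96 lower at an unadjusted p under 0.05. The counts that follow are therefore those adjusted over the list alone.

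Detoxification genes rose as lists. Of 23 glutathione S-transferases, enzymes that join glutathione to reactive compounds, 12 rose when adjusted over the list alone, with a mean log2 ratio of 2.15 (camera adjusted p = 5.61e-06; adjusted p = 0.693 with an estimated correlation). The mean was 3.02 on replicate 1 and 1.27 on replicate 2. GSTU24 was at 5.14 ± 1.95, GSTU19 at 4.50 ± 1.04, GSTU7 at 4.44 ± 1.75 and GSTU25 at 4.21 ± 3.27; members of this family lie in tandem and resemble each other, so single names are uncertain. Of 20 other detoxification genes 14 rose when adjusted over the list alone, with a mean of 2.99 (camera adjusted p = 6.24e-08; adjusted p = 0.693 with an estimated correlation). The mean was 4.00 on replicate 1 and 1.97 on replicate 2. The transporter gene ABCG40 was at 5.21 ± 2.67, the glycosyltransferase gene UGT74E2 at 4.78 ± 3.49, the reductase gene OPR1 at 4.72 ± 1.1 and the cytochrome P450 gene CYP81D11 at 4.68 ± 1.00. In single-channel values, which are open to dye bias, the named genes of both lists were higher in the control of replicate 2 than in that of replicate 1. ABCG40 was at 7.4 and 11.73 in the controls of replicates 1 and 2, against 14.5 and 15.06 in the treated samples. Of 17 oxidative stress genes 10 rose when adjusted over the list alone, with a mean of 2.16 (camera adjusted p = 6.9e-06; adjusted p = 0.693 with an estimated correlation). Here replicate 1 had a mean of 2.91 and replicate 2 of 1.41. The ascorbate peroxidase gene APX2 was at 4.64 ± 0.12, DHAR2, for dehydroascorbate reductase, at 4.13 ± 1.22, the zinc finger gene ZAT12 at 3.84 ± 1.86 and BAP1 at 3.40 ± 1.70. Sulfate assimilation and glutathione synthesis had a mean of 2.26, with 8 of 10 members up when adjusted over the list alone (camera adjusted p = 2.89e-06; adjusted p = 0.693 with an estimated correlation). LSU1 and LSU2, which respond to sulfur supply, were at 4.82 ± 0.75 and 2.88 ± 0.12, and the APS reductase genes APR3 and APR1 at 3.38 ± 0.83 and 3.13 ± 0.46.

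Glucosinolate genes, for the sulfur-rich defence compounds of the mustard family, fell as a list. Of 17 members 15 fell when adjusted over the list alone, with a mean of -2.18 (camera adjusted p = 2.05e-08; adjusted p = 0.693 with an estimated correlation). CYP83A1, of the aliphatic branch, was at -3.78 ± 0.83, the chain-elongation genes MAM3 and MAM1 at -3.64 ± 0.30 and -2.94 ± 0.16, and the regulator MYB34 at -3.07 ± 0.53. The phenylpropanoid and flavonoid list fell, with a mean of -0.72 over 16 members (camera adjusted p = 0.00745; adjusted p = 0.693 with an estimated correlation). The mean was -0.36 on replicate 1 and -1.08 on replicate 2. PAL1 was at -1.75 ± 2.28, CHS at -1.55 ± 0.57, FLS1 at -1.55 ± 0.54 and 4CL1 at -1.46 ± 0.65, and 11 members were lower on both arrays. Root markers fell as a list, with a mean of -1.21 and 7 of 14 members down when adjusted over the list alone (camera adjusted p = 8.98e-05; adjusted p = 0.693 with an estimated correlation). COBL9, of root hairs, was at -2.88 ± 0.43, RCI3 at -1.92 ± 0.49, EXPA7 at -1.88 ± 0.36 and CASP1, of the Casparian strip, at -1.73 ± 0.67.

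**Figure D2:**
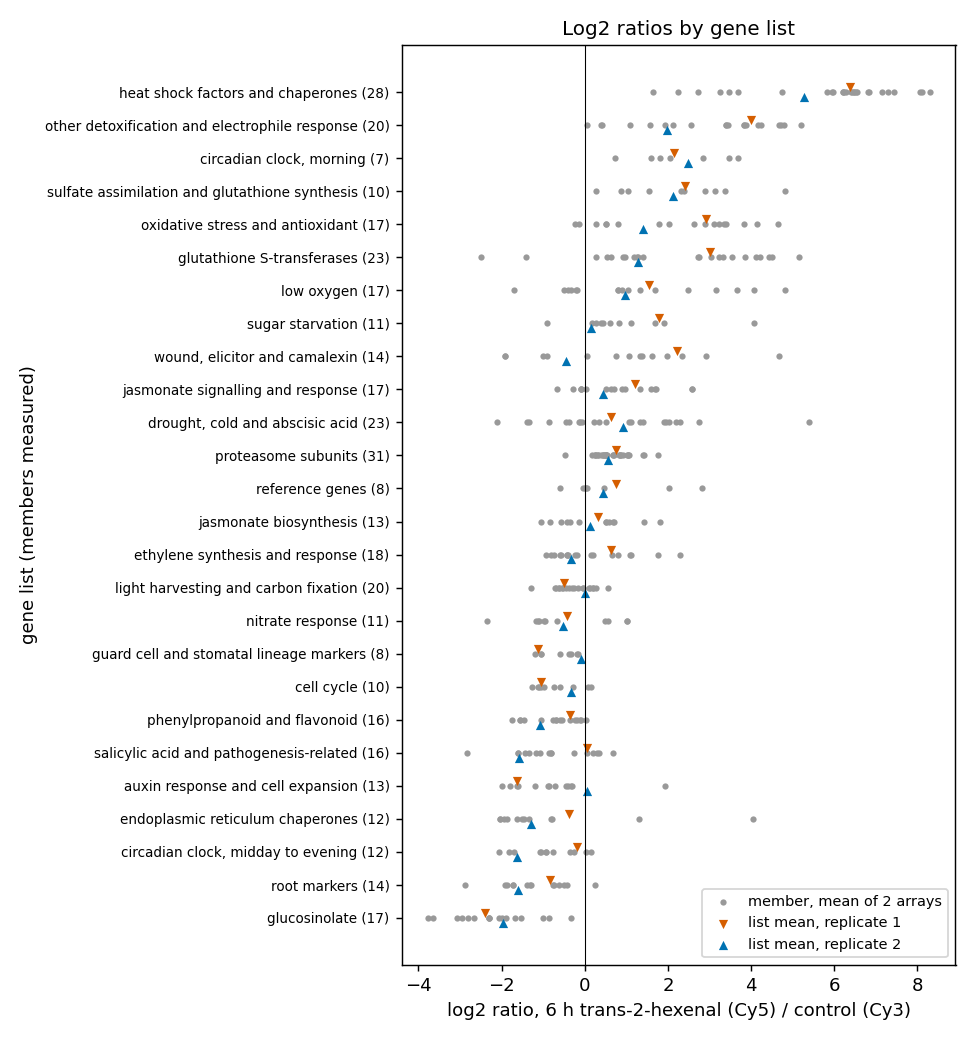
Log2 ratios of treated over control (x axis) for the members of 26 gene lists (y axis, number measured in brackets; the cytosolic ribosomal list is not drawn), with a grey point per gene and triangles for the list mean on each array. The heat shock list is highest on both arrays and the glucosinolate list lowest on the mean of both, at -2.18.

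Jasmonate signalling rose as a list, with a mean of 0.83 (camera adjusted p = 0.0261; adjusted p = 0.693 with an estimated correlation), with 1.21 on replicate 1 and 0.44 on replicate 2, and 1 of 17 members rose when adjusted over the list alone. JAZ7 was at 2.59 ± 1.24, TAT3, well above background in 1 of 2 controls, at 2.57 ± 0.68, JAZ10 at 1.72 ± 1.73, and JAZ5, not well above background in either control, was at least 3.22-fold higher on the mean of the arrays (adjusted p = 0.152), with log2 ratios of 2.62 and 0.75 on replicates 1 and 2. This call was lost in 2 of 10 other settings, median centring and the stricter filter (adjusted p from 0.0188 to 0.0736 over the 10), with list means of 1.19, or 0.90 relative to the median of all genes, and 0.65. Jasmonate biosynthesis did not pass, at a mean of 0.22 (camera adjusted p = 0.578), with 0.31 on replicate 1 and 0.13 on replicate 2. ACX1 was at 1.82 ± 0.61, LOX4, well above background in 1 of 2 controls, at 1.42 ± 1.48, AOC4 at -1.04 ± 0.83 and AOS at -0.83 ± 0.58. The salicylic acid list had a mean of -0.76 (camera adjusted p = 0.0451; adjusted p = 0.693 with an estimated correlation), which came from replicate 2 at -1.57, with replicate 1 at 0.05. The call was lost in 5 of 10 other settings (adjusted p from 0.0138 to 0.0856), with means from -0.76 to -0.68 in those 5, and 2 of 16 members fell when adjusted over the list alone. FMO1 was at -2.82 ± 0.70, WRKY54 at -1.61 ± 0.47, PBS3 at -1.60 ± 2.63 and NIMIN1 at -1.43 ± 3.96. The ethylene list did not pass (camera adjusted p = 0.861), with a mean of 0.15, a median of -0.21 and a test direction of down. The mean was 0.64 on replicate 1 and -0.34 on replicate 2. ERF6 was at 2.30 ± 1.36, ACS7 at 1.76 ± 3.45, ERF2 at 1.12 ± 0.73 and ERF5 at 1.08 ± 1.04. The wound, elicitor and camalexin list did not pass (mean 0.88, camera adjusted p = 0.24), with 2.21 on replicate 1 and -0.45 on replicate 2, and 2 of 14 members rose when adjusted over the list alone. CML37 was at 4.67 ± 2.08, WRKY40 at 2.92 ± 3.03, TCH4 at 2.33 ± 1.56 and PAD3 at 1.99 ± 0.62.

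The drought, cold and abscisic acid list rose, with a mean of 0.77 (camera adjusted p = 0.0186; adjusted p = 0.693 with an estimated correlation) and 10 members up and 1 down of 23 when adjusted over the list alone. The transcription factor gene DREB2A was at 5.39 ± 1.5, the phosphatase gene ABI2 at 2.74 ± 0.23, DREB2B at 2.30 ± 0.88 and COR47 at 2.2 ± 0.23. On both arrays 12 members were higher and 2 lower. The lower ones were RAB18 at -2.1 ± 0.26, the member that fell, and CBF3 at -1.35 ± 1.23. Some members had opposite signs on replicates 1 and 2. COR15A was at -2.9 and 1.99, COR15B at -3.25 and 0.47, RD22 at -2.03 and 0.3, and RD29A at -1.44 and 0.68. The rise was thus not shared by all members. Low oxygen genes rose as a list, with a mean of 1.26 (camera adjusted p = 0.0157; adjusted p = 0.693 with an estimated correlation) and 9 up and 1 down of 17 when adjusted over the list alone. SRO5 was at 4.82 ± 1.12, HRE2, well above background in 1 of 2 controls, at 4.06 ± 1.47, PDC1, for pyruvate decarboxylase, at 3.66 ± 0.82 and ADH1, for alcohol dehydrogenase, at 3.15 ± 0.29. Both calls were lost in 1 of 10 other settings, median centring (adjusted p from 0.0126 to 0.139 and from 0.0119 to 0.0667 over the 10), where the means were 1.19 and 1.57, or 0.90 and 1.28 relative to the median of all genes in place of 0.81 and 1.30.

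Clock genes that peak in the morning rose as a list. All 7 members rose when adjusted over the list alone, with a mean of 2.31 (camera adjusted p = 8.37e-06; adjusted p = 0.693 with an estimated correlation). CCA1 was at 3.68 ± 0.74, RVE1 at 3.46 ± 0.17, LHY at 2.85 ± 0.16 and PRR9 at 2.04 ± 0.37. Midday to evening clock genes had a mean of -0.90 (camera adjusted p = 0.0147; adjusted p = 0.693 with an estimated correlation), at -0.18 on replicate 1 and -1.62 on replicate 2. ELF4 was at -2.05 ± 2.01, CCR2 at -1.82 ± 0.69, PRR3 at -1.70 ± 0.98 and CCR1 at -1.07 ± 0.16. The sugar starvation list had a mean of 0.97 (camera adjusted p = 0.0418; adjusted p = 0.693 with an estimated correlation), with 1.78 on replicate 1 and 0.15 on replicate 2, and 1 of 11 members rose when adjusted over the list alone. The call was lost in 3 of 10 other settings (adjusted p from 0.0288 to 0.0667), with means from 0.91 to 1.52. DIN2 was at 4.08 ± 0.09, TPS11 at 1.90 ± 1.26, ASN1 at 1.70 ± 1.84 and DIN1 at 1.11 ± 1.33. The nitrate response list did not pass, with a mean of -0.48 (camera adjusted p = 0.133); with median centring it was 0.01, or -0.28 relative to the median of all genes. On both arrays 7 members were lower and 4 higher. Adjusted over the list alone, 5 of 11 members fell; NRT2.1, for a nitrate transporter, was at -2.35 ± 0.26, G6PD3 at -1.16 ± 0.21, LBD39 at -1.13 ± 0.50 and RFNR2 at -1.1 ± 0.43.

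Light harvesting and carbon fixation did not pass, with a mean of -0.25 (camera adjusted p = 0.208), at -0.50 on replicate 1 and 0.00 on replicate 2; with median centring it was 0.20, or -0.09 relative to the median of all genes. It passed in 1 of 10 other settings, the mean of all probes, where the list mean was -0.49 (camera adjusted p from 0.00662 to 0.755 over the 10). LHCB1.4 was at -1.30 ± 0.44, LHCB4.2 at -0.71 ± 0.85, LHCA2 at -0.69 ± 0.29 and LHCB3 at -0.61 ± 0.90, and names within the LHCB1 family are uncertain. The auxin and cell expansion list had a mean of -0.78 (camera adjusted p = 0.0278; adjusted p = 0.693 with an estimated correlation), which came from replicate 1 at -1.63, with replicate 2 at 0.06. EXPA8 was at -2.0 ± 3.58, GH3.3 at 1.94 ± 2.83, IAA3 at -1.80 ± 1.19 and EXPA1 at -1.62 ± 1.68. Cell cycle genes fell as a list, with a mean of -0.69 (camera adjusted p = 0.0186; adjusted p = 0.693 with an estimated correlation). Replicate 1 had a mean of -1.05 and replicate 2 of -0.33. KNOLLE was at -1.26 ± 0.82, CYCB1;2 at -1.13 ± 0.60, CYCA1;1 at -1.1 ± 1.00 and CDKB2;1 at -1.04 ± 0.50. Guard cell and stomatal lineage markers did not pass (mean -0.62, camera adjusted p = 0.052), though they did in 3 of 10 other settings (adjusted p from 0.0127 to 0.0703). The mean was -1.13 on replicate 1 and -0.10 on replicate 2. KAT1 was at -1.20 ± 1.28, FAMA at -1.05 ± 0.24, MYB60 at -1.05 ± 0.41 and TMM at -0.59 ± 1.29. Adjusted over the list alone, 0 members passed in limma in the jasmonate biosynthesis, ethylene, phenylpropanoid, light harvesting, midday to evening clock, auxin, cell cycle, guard cell, ribosomal and proteasome lists. At an unadjusted p under 0.05 the largest groups among these were 33 lower and 4 higher ribosomal protein genes, 14 higher proteasome genes, 5 lower cell cycle genes and 4 lower evening clock genes.

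In total 20 of 27 lists passed, 11 up and 9 down. Median centring moved the means of 10 of these 20 by over 1.5 times, but relative to the median of all genes only that of the ribosomal list. Besides the endoplasmic reticulum and ribosomal lists these were drought at 1.19, sugar starvation at 1.52, proteasome at 1.2, salicylic acid at -0.40, phenylpropanoid at -0.44, midday to evening clock at -0.39, auxin at -0.46 and cell cycle at -0.45. Of the lists that did not pass, jasmonate biosynthesis stood at 0.67, ethylene at 0.62, wound at 1.35 and the reference genes at 1.11. With an estimated correlation 0 lists passed in camera, and 0 had an unadjusted p under 0.05; fry called 0, with 6 at an unadjusted p under 0.05. The correlation was estimated from 1 residual per gene. For the 26 lists other than the ribosomal one, the median difference between the replicates was set against 10000 random lists. It lay at percentile 100 in 12 lists and at percentile 0 in 3, so members of these lists tended to differ between the arrays together.

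Across genes, which are not independent replicates, the log2 ratios of the 2 arrays had a Pearson correlation of 0.699 and a Spearman correlation of 0.672. Of the 17 genes 100% had the same sign on both arrays, which is no separate support, since passing the test with 2 arrays favours ratios that agree. The ratios spread more widely on replicate 1 (SD 1.23 over genes) than on replicate 2 (SD 0.93). The spike-in controls gave, in the scanner's own statistics, slopes of observed on nominal log ratio of 0.897 and 0.918 on replicates 1 and 2. The correlations were 0.931 and 0.967. The intercepts were 0.169 and 0.051 in log10, an offset towards Cy5 that differed between the arrays. These describe the scanner's ratios. After the background correction and loess used here all 10 spike-ins lay nearer to 0 on both arrays, with E1A_r60_a22 at 2.97 and 2.74 in place of 3.21 and 3.04, and E1A_r60_a97 at 0.65 and 0.47 in place of 2.72 and 2.18. Of 8 reference genes, with a mean of 0.60 (camera adjusted p = 0.273), 4 lay within 0.06 of 0: PP2AA3 at -0.03 ± 0.01, SAND at 0.02 ± 0.15, TIP41 at 0.01 ± 0.06 and UBC21 at 0.06 ± 0.00. GAPC1, a glycolytic enzyme, stood at 2.81 ± 0.66 and UBQ10, for ubiquitin, at 2.03 ± 0.63, and both passed when adjusted over the list alone; EF1A was at -0.59 ± 0.14 and ACT2 at 0.47 ± 0.53.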

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

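The probes named here were chosen after their values were seen. Among the probes that the array ties to no locus code, which entered no comparison, 2146 passed the filter on dim probes. Of these, 169 were at least 2-fold higher in the treated channel on both arrays and 33 at least 2-fold lower. Of the 20600 genes tested, 1644 were higher and 1022 lower by the same rule. Among the probes without a locus code the share higher was thus similar and the share lower was smaller. The highest was TA25950_3702, described as unknown, at a log2 ratio of 4.79 ± 1.21 (SD, n = 2), and the next CB185540, a partial match to PMZ, at 4.67 ± 2.06. Among the lowest were BP581534, a partial match to a peroxidase precursor, at -2.73 ± 0.52, and TC309495, a partial match to a glycine-rich RNA-binding protein, at -2.71 ± 0.13. These probes were not matched to loci here.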

How the results depend on the processing

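Chosen after seeing the data were the threshold of 0.10 and the heat shock list without its small heat shock proteins. Against 17 genes, all up, limma called 17 with no background subtraction, with an offset of 16, with a trended prior (16 of them shared) and with TREAT, and 18 with the stricter filter or with the mean of all probes. It called 0 with the deposited log10 ratio, the deposited value table or no filter, with smallest adjusted p-values of 0.0585, 0.0594 and 0.0908; the counts at an unadjusted p under 0.05 were 6353, 6344 and 7437. Median centring gave 1481 genes, 1272 up and 209 down, all at least 2-fold, and moved the median of all genes from -0.04 to 0.29. Relative to that median the heat shock list stood at 6.10 in place of 5.87 and the glucosinolate list at -2.07 in place of -2.14. With no replicate block, in which the pairing of channels on an array is ignored, 3469 genes passed, and 2821 of these at least 2-fold. A threshold of 0.10 gave 2828 genes, 1714 up and 1114 down. With 1 array left there is no test, and 3893 to 6436 genes were at least 2-fold different on it. The cause of these differences was not tested. A slide term was not run, since both arrays share a slide.

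Of 27 lists, 20 passed camera, and 16 to 21 under the other processing choices. With an estimated correlation or with fry, 0 passed (0 and 6 at an unadjusted p under 0.05). Of the 20 lists, 18 kept their sign on both single arrays, and 19 on each taken alone. The auxin list ranged from -1.63 without replicate 2 to 0.06 without replicate 1, and the salicylic acid list from -1.57 without replicate 1 to 0.05 without replicate 2. Median centring put light harvesting at 0.20, nitrate response at 0.01 and the cytosolic ribosomal proteins at 0.17; relative to the median of all genes these were -0.09, -0.28 and -0.12, so the sign turned with the common shift. The 16 heat shock members that are not small heat shock proteins had a mean of 5.07 (camera adjusted p = 9.6e-12; adjusted p = 0.693 with an estimated correlation). The Pearson and Spearman correlations of the arrays were 0.739 and 0.717 with median centring and 0.689 and 0.637 with no filter. The reference genes had a mean of 1.11 with median centring. All 123 named genes kept their direction in the settings that use both arrays and measured them. In each of the settings with 0 genes 10 lost their call, while 47 gained one with median centring and 64 with no replicate block. Probes near background limit ratios of weak genes.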

Other observations

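The tests of families taken from the array's descriptions, the test of cross-hybridisation, the test of random noise and the tests of noise near background with no filter and in the remaining genes were chosen after the results were seen. Of 25 families tested, 12 passed camera, 4 up and 8 down, and 0 passed with an estimated correlation or with fry (0 and 4 at an unadjusted p under 0.05). The families named here kept their direction with median centring and with the deposited log10 ratio. Median centring put receptor kinases, peroxidases, aquaporins, pectin methylesterases and ubiquitin ligases at -0.47, -0.48, -0.52, -0.51 and 0.79. Relative to the median of all genes these were -0.76, -0.77, -0.81, -0.80 and 0.50, in place of -0.67, -0.79, -0.79, -0.72 and 0.49. Leucine-rich repeat receptor kinases, a large class of cell surface receptors, were lower as a family, with a mean log2 ratio of -0.71 over 126 genes and 86 lower on both arrays (camera adjusted p = 2.68e-08; adjusted p = 0.8 with an estimated correlation). Peroxidases had a mean of -0.83 over 82 genes, of which 33 were lower and 6 higher when adjusted over the family alone (camera adjusted p = 2.12e-05; adjusted p = 0.8 with an estimated correlation). Aquaporins, the water channels, were at -0.83 over 18 genes, 12 lower on both arrays (camera adjusted p = 0.00306; adjusted p = 0.8 with an estimated correlation), and pectin methylesterases at -0.76 over 42 genes (camera adjusted p = 0.00162; adjusted p = 0.8 with an estimated correlation). Root markers were lower too, with a mean of -1.21 and 12 of 14 lower on both arrays, the peroxidase gene RCI3 at -1.92 ± 0.49 among them. U-box and RING ubiquitin ligases were higher, at 0.45 over 266 genes (camera adjusted p = 0.00115, and 0.8 with an estimated correlation). Of these, 144 were higher and 65 lower on both arrays, with means of 0.62 and 0.28 on replicates 1 and 2.

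On replicate 1, 135 genes were at least 2-fold higher while at least 2-fold lower on replicate 2, and 25 the other way round. Genes picked out after their values were seen include FRK1, a receptor kinase gene induced by elicitors, at 2.54 and -4.56 on replicates 1 and 2, ICS1, for salicylic acid synthesis, at 1.59 and -4.28, and the expansin gene EXPA8 at -4.54 and 0.53. The wound, elicitor and camalexin list had medians of 2.58 and -0.31, and the salicylic acid list 0.38 and -1.12. In all, 7 of 26 lists had medians of opposite sign on the arrays, the ethylene, sugar starvation, jasmonate biosynthesis, light harvesting and guard cell lists being the others. This describes the 2 arrays. In single-channel values, which are open to dye bias, the gap lay mainly in the controls for some named genes. Among these were all the genes named from the glutathione S-transferase and other detoxification lists, with the control of replicate 2 higher. UGT74E2 was at 9.78 and 15.15 in the controls of replicates 1 and 2, against 17.04 and 17.46 in the treated samples. EXPA8 was at 13.8 and 10.09 against 9.26 and 10.63. For GH3.3 the gap lay mainly in the treated samples, with 8.74 and 7.98 against 8.68 and 11.93. The source of the gap was not tested.

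Of the 2666 genes at least 2-fold different the same way on both arrays, dye bias tied to single probes would put the sign of another probe of the gene at chance. Of 698 such genes with another kept probe, 98.6% had the same sign on the next brightest one (exact binomial 95% interval 97.4 to 99.3), and 98.5% of the 677 whose probes share no 20 bases. This argues against such dye bias for the genes covered. The same sign with a change of at least 2-fold on that probe was seen in 80.1% and 79.8%. The rest of the 2666 genes had no other kept probe. Random noise, independent between the arrays, is argued against by the 94.3% of 2826 genes at least 2-fold different on both arrays that differed the same way (interval 93.4 to 95.2). Of the pattern's genes, 89.8% were well above background in both channels of both arrays (interval 88.6 to 90.9), which argues against noise near background for those genes. That share was slightly below the 92.4% of all genes tested, so it does not set the pattern apart from other genes. With no filter on dim probes the shares were 89.8% and 65.6%. This comparison cannot decide, since dim probes hardly reached 2-fold on both arrays at the offset of 50. Without the filter 29025 genes were tested in place of 20600, but the pattern held 2667 genes in place of 2666. Noise near background stays open for the other 272 genes, of which 5 had another probe well above background throughout. A dye effect shared by a whole transcript stays open too, since no dye swap was made and the treatment cannot be separated from it.

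The rise of the heat shock list was set against cross-hybridisation among small heat shock proteins and against a general shift of chaperones. The 12 members outside the small heat shock protein, HSP70 and HSP90 families that were measured by a probe of a single locus had a median log2 ratio of 5.37, from 1.63 to 7.29, and 100% passed when adjusted over the list alone, which argues against the first. The median of the heat shock list lay 6.30 above the higher of those of the endoplasmic reticulum chaperones (-1.49) and the reference genes (0.04). Of the 12 genes of the endoplasmic reticulum list 10 were lower and 2 higher on both arrays, which argues against a rise shared by all chaperones. The reference genes cannot decide on a shift of scale, since loess sets most genes near 0 before the comparison. The aldehyde remains a candidate cause as a hypothesis, beside the handling of the seedlings, since no sample kept for 6 h without trans-2-hexenal was analysed here.

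The clock, nitrate and sugar starvation lists bear on the time and the transfer that separate treated from control seedlings. If the hours between the samples were the cause, the clock lists would part. They did part, with a median of -0.94 for the midday to evening list and 2.04 for the morning list. The evening median was -0.10 on replicate 1 and -1.55 on replicate 2. The prediction set no direction, and which list would rise depends on the time of day at 0 h. That time was not taken into account here, so the parting cannot decide whether the hours were the cause. If the move from agar to water were the cause, nitrate genes would be low and sugar starvation genes high: the medians were -0.95 and 0.61, which is consistent with it on the mean of both arrays. However, the sugar starvation median was 1.44 on replicate 1 and -0.34 on replicate 2, so that part rests on replicate 1. The nitrate median was -0.81 and -0.41, and the list did not pass (camera adjusted p = 0.133). Its mean was -0.48, or 0.01 with median centring. Of its 11 genes 4 were higher on both arrays, NIA2 at 1.02 and NIA1 at 1.01 among them. Root markers were lower too, with a mean of -1.21. The share of root in the samples was not tested, so these medians do not single out the transfer. An effect of trans-2-hexenal on these genes stays open and was not tested.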
